A study of Homo sapiens with 3 samples.

How the data were processed

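The series measured N6-methyladenosine (m6A), a base modification of mRNA, in P493-6 cells, an established human B cell line in which tetracycline switches off a MYC transgene. Of its 3 samples, 1 was an antibody-enriched library of cells at 0 h of tetracycline, 1 was an antibody-enriched library of cells after 72 h of tetracycline at 1 ug/ml, and 1 was an unenriched input library at 0 h. Per the labels' protocols, mRNA was selected on beads, fragmented, and incubated with a polyclonal antibody against m6A before sequencing libraries were made. The groups were taken from the sample titles. A peak list of each of the 2 enriched libraries was used, and values of the input library were not used here. No input library at 72 h is among the samples, so the fold enrichment at 72 h cannot rest on a matched input from them.

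Each deposited list holds 1 line per peak, with its chromosome, start, end, strand, a gene identifier and symbol, a gene type, 6 transcript-region flags set to 0 or 1, and a fold enrichment. The fold enrichment was taken as the authors' own linear ratio of each peak. Which libraries stand behind that ratio, how it was normalised and which threshold was set are not given in the sources used here. The lowest ratio was 5.00 at 0 h and 5.01 at 72 h. The submitters' processing notes name Bowtie, TopHat2 version 2.0.9, HOMER and MACS2 version 2.0.10 and the genome build hg19. Which of these tools made which step is not given in the sources used here. The peaks of each list carry running numbers that reach 7494 at 0 h and 3777 at 72 h, and 405 and 185 of these numbers have no peak in the lists. The reason is not given in the sources used here. The deposited gene symbols were used as they stand, and 4334 of the 4603 symbols at 0 h and 2375 of the 2533 at 72 h matched a RefSeq symbol or a unique synonym. Start positions are printed 1-based, on the reading that the files follow the BED convention.

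The lists give no read counts, so the sequencing depth of both libraries is unknown, and no depth correction was possible. The number of peaks depends on depth and on the abundance of each transcript, and a gene without a listed peak may still be methylated. The fold enrichment was used only to describe, rank or filter peaks within a list. Each condition had 1 library, so no test between conditions was made and no p-value is given. Shares carry 95% Wilson intervals, which cover counting error only.

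Peaks were compared with bedtools 2.31.1, where an overlap of at least 1 bp on the same strand counted as shared. A gene was taken as called in a library when at least 1 peak was assigned to it in the deposited annotation. The 18 gene lists were fixed before the data were examined. For each list, the members with a peak were counted as called in both libraries, only at 0 h or only at 72 h. The balance of a list was the number called only at 72 h minus the number called only at 0 h, divided by the number with a peak. It was placed as a percentile among 10000 random lists of the same size drawn from all 5145 genes with a peak, with ties counted at their middle. Percentiles under 2.5 or over 97.5 were taken as standing apart. This describes these 2 libraries and is not a test between conditions, and transcript abundance could not be matched.

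The genes named were chosen by a rule set before the data were examined. The rule took the 4 study genes SPI1, PHF12, MYC and ALKBH5, and the 10 genes called only at 0 h and the 10 called only at 72 h with the highest fold enrichment. It also took the 5 genes called in both with the highest fold enrichment in each list. From each gene list it took up to 4 members called only in each library and up to 2 called in both, by the same value. Some genes that the rule took are not reported here. Other genes are named only where the text says that they were chosen after their values were seen.

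The overlap step was tested on simulated data, in which 2135 of the 7089 peaks at 0 h were moved by 10 bp and the rest away. All 2135 were found again, with 0 false overlaps. Of 200 simulated lists of 22 genes, each gene drawn with the chances seen in the NF-kB list, 195 lay above the 97.5th percentile, against 10 of 200 lists drawn at random from the 5145 genes. The alternatives were a reciprocal overlap of 50%, a distance of up to 100 bp, merged peaks, the more enriched peaks of each list, lists of equal length, only peaks with a transcript-region flag, and genes counted as shared only where their peaks overlapped. Further alternatives were set after the data were seen, namely overlap regardless of strand, random lists of mRNA genes only, gene lists without genes whose peaks in both libraries did not overlap, shared peaks assigned to different genes, and random lists matched on the rank of each gene's highest fold enrichment in 10 equal parts. Motifs under peaks and gene assignment from a reference annotation were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.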

Results

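N6-methyladenosine (m6A) peaks were compared in P493-6 cells, a human B cell line that models Burkitt's lymphoma and carries a MYC transgene that tetracycline switches off. Without tetracycline (Tet 0 h) MYC was high, and after 72 h at 1 ug/ml (Tet 72 h) it was low. The study asked how the MYC level affects m6A on mRNA. The data were 2 lists of peaks, 1 per condition, each from 1 library enriched with an antibody against m6A, so no difference between conditions has a replicate check. The depth of both libraries is unknown. Positions are given in the genome build hg19, and the fold enrichment quoted for a peak is the authors' own value within its list, not a change between conditions.

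The first comparison asked which transcripts carried listed peaks with MYC high and with MYC low. Genes with a peak at Tet 0 h outnumbered those at Tet 72 h, 4603 against 2533, and most of the latter belonged to both sets. Peaks only at Tet 0 h lay on RBBP4, a histone-binding chromatin protein, and on TIMM50, a subunit of the mitochondrial protein import machinery. Peaks only at Tet 72 h lay on IFI27, an interferon-induced gene, on HMOX1, which encodes the heme-degrading enzyme heme oxygenase, and on MXD4, a partner of MAX that represses transcription at MYC target sites. Genes with peaks in both included PPP1R7, a regulator of protein phosphatase, and RANBP1, a regulator of the nuclear transport GTPase RAN.

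The Tet 0 h library had 7089 peaks and the Tet 72 h library 3592, a ratio of 1.97. Peaks at Tet 0 h were overlapped by a Tet 72 h peak in 32.0% of cases (2271 peaks, 95% Wilson interval 31.0 to 33.1%). Peaks at Tet 72 h were overlapped by a Tet 0 h peak in 63.3% (2273 peaks, 61.7 to 64.8%). These intervals, like all others here, cover counting error only. Peaks were called on 5145 genes in either library, of which 1991 had peaks in both, 2612 only at Tet 0 h and 542 only at Tet 72 h. Thus 78.6% of the genes with a peak at Tet 72 h (77.0 to 80.2%) also had one at Tet 0 h, and 43.3% of those at Tet 0 h (41.8 to 44.7%) also had one at Tet 72 h. The excess at Tet 0 h depended on the list length. With the Tet 0 h list reduced to its 3592 most enriched peaks, 1288 genes had a peak only at Tet 0 h and 1079 only at Tet 72 h. The overlapped share was then 41.2% of the Tet 0 h peaks and 41.3% of the Tet 72 h peaks. This reduction kept Tet 0 h peaks down to about the list's median fold enrichment of 11.1, but Tet 72 h peaks down to 5.01. A gene called only at Tet 72 h at equal list lengths can therefore have a weaker listed peak at Tet 0 h.

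Among the 1991 shared genes, 1751 (87.9%) had at least 1 peak that overlapped a peak of the other library, and 240 had peaks at separate positions only. The shared genes held 3814 peaks at Tet 0 h and 2962 at Tet 72 h, a ratio of 1.29 with an interval of 1.25 to 1.32 from resampling the genes. More peaks were listed at Tet 0 h for 710 of them, more at Tet 72 h for 185, and as many in both for 1096. TCOF1, a ribosome biogenesis factor of the nucleolus, had 8 peaks at Tet 0 h and 3 at Tet 72 h. TCF3, a B cell transcription factor, had 7 and 4. The genes with the most peaks, named after their values were seen, were SMARCA4, a chromatin remodelling ATPase, with 13 at Tet 0 h, and ANKRD11, a chromatin regulator, with 12 at Tet 72 h. The share of genes with more than 1 peak was 32.2% at Tet 0 h and 26.9% at Tet 72 h, and in the reduced Tet 0 h list it was 21.3%.

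Genes with a peak only at Tet 0 h and a high fold enrichment included TXLNG with 54.8, the HLA pseudogene HLA-H with 54.4, RBBP4 with 50.1, PRKRIP1 with 48.9 and the RNA helicase gene DDX47 with 47.5. ANP32A had 45.4, the processed pseudogene RP11-216M21.1 had 45.2, MNF1 (now UQCC2, an assembly factor of respiratory complex III) had 45.2 and TIMM50 had 45.0. Of the genes with a peak only at Tet 72 h, an mRNA gene with the identifier ENSG00000243716, listed under a clone name, came first with a fold enrichment of 49.1. IFI27 had 46.0, HMOX1 had 44.4, the ribosomal protein gene RPS19 had 37.8, CTB-133G6.1 had 37.2 and the calponin gene CNN2 had 35.8. RN7SL3, a copy of the signal recognition particle RNA, had 35.5, MXD4 had 33.9, NBPF8 had 31.7 and OST4 had 31.4. HLA-H, RP11-216M21.1, NBPF8 and RN7SL3 have near-identical copies elsewhere in the genome, so the gene assignment of their peaks is uncertain. The other genes named here, ENSG00000243716 included, were not checked for such copies.

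Among genes with peaks in both libraries, PPP1R7 ranked first at Tet 0 h with a fold enrichment of 90.8. RANBP1 with 85.7, NDUFA8, a subunit of respiratory complex I, with 81.4, ABCF1 with 77.7 and SNRNP25 with 74.5 came next. At Tet 72 h the first was ARPC1B, a subunit of the actin-nucleating ARP2/3 complex, with 68.0. MAB21L3 with 61.0, OGFR with 60.5, SLC15A3 with 59.2 and PIN4 with 55.7 followed.

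Overlap rose with enrichment within each list. With each list ranked by fold enrichment and divided into 10 equal parts, 21.2% (18.3 to 24.3%) of the lowest part at Tet 0 h were overlapped by a Tet 72 h peak, against 59.5% (55.9 to 63.1%) of the highest. At Tet 72 h the share was 60.0% (54.9 to 64.9%) in the lowest part, 50.4% in the next and 83.6% (79.4 to 87.1%) in the highest. The median fold enrichment of overlapped peaks was 13.7 at Tet 0 h, against 10.2 for those not overlapped, and 11.4 against 9.25 at Tet 72 h. The median width was 132 bp in both lists.

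**Figure D1:**
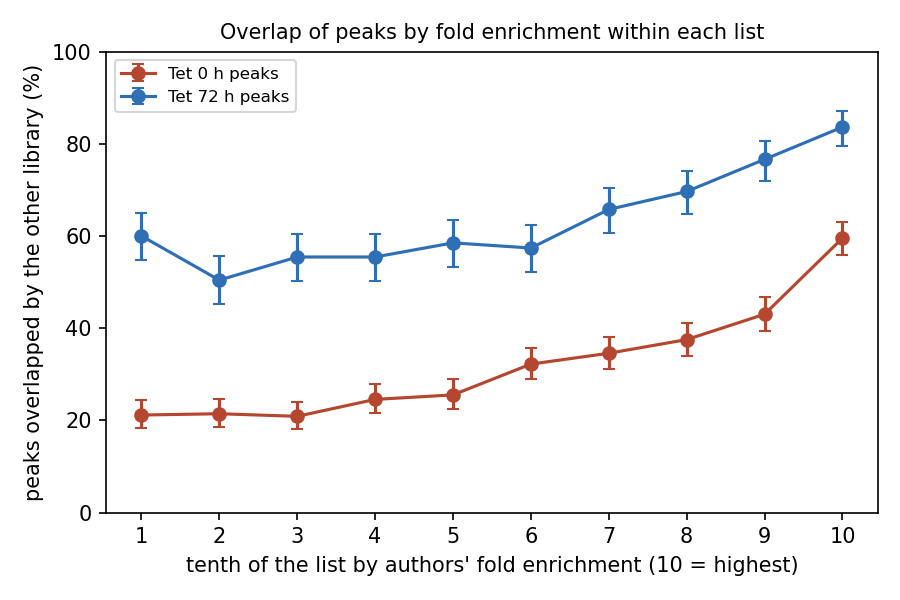
Share of peaks (%) overlapped by a peak of the other library, for each of 10 equal parts of a list ranked by the authors' fold enrichment, with 95% Wilson intervals as bars. Tet 0 h peaks rise from 21.2% in the lowest to 59.5% in the highest part, and Tet 72 h peaks lie at 60.0% and 83.6%.

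The next comparison asked whether the position of peaks along transcripts differed. Coding sequence was flagged for most peaks in both libraries, 75.2% at Tet 0 h and 74.9% at Tet 72 h, and 5' untranslated regions for 18.4% and 18.1%. The 3' untranslated region was flagged for 16.1% (15.3 to 17.0%) at Tet 0 h and 14.7% (13.6 to 15.9%) at Tet 72 h. Coding starts were flagged for 12.2% in both, coding ends for 6.63% and 6.04%, and the region the annotation calls TcSS for 2.75% and 3.06%. No flag was set for 8.89% (8.25 to 9.57%) and 10.1% (9.19 to 11.2%). The intervals of the 2 libraries overlapped for all 6 flags and for peaks with none in the whole lists. In the more enriched 50% of each list, peaks with no flag were 7.08% (6.28 to 7.97%) at Tet 0 h and 9.86% (8.56 to 11.3%) at Tet 72 h, and these intervals did not overlap. With only the Tet 0 h list reduced, to its 3592 most enriched peaks, its shares of 5' untranslated regions (26.6%), coding starts (18.0%), 3' untranslated regions (11.5%) and no flag (7.04%) had intervals apart from those of the whole Tet 72 h list. That sets enriched peaks against a whole list, and these flags shifted with enrichment. In the more enriched 50% of each list, 5' untranslated regions were 26.7% at Tet 0 h and 27.7% at Tet 72 h, and coding starts 18.1% and 19.0%. The 3' untranslated regions were 11.5% and 9.63%, and the intervals of these regions overlapped between libraries. A peak can carry several flags, and the coding flag was also set on 278 peaks of genes not typed as mRNA at Tet 0 h and 143 at Tet 72 h, so it does not always mean coding sequence.

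**Figure D2:**
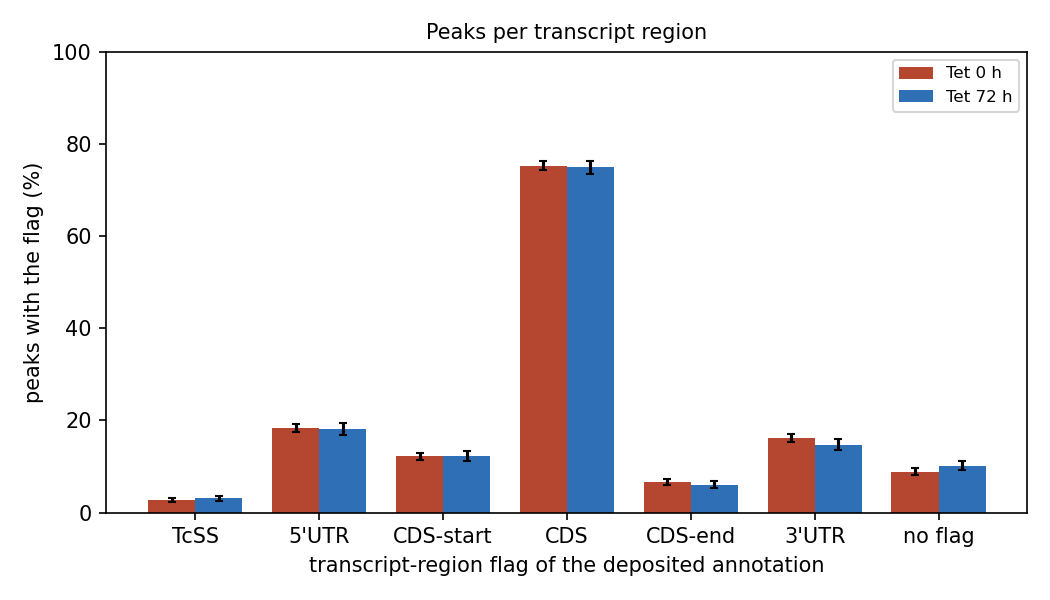
Share of peaks (%) with each transcript-region flag of the deposited annotation at Tet 0 h and Tet 72 h, with 95% Wilson intervals as bars. The coding sequence flag leads in both libraries, at 75.2% and 74.9%.

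Peaks of 4 genes tied to the study were then examined. SPI1, which encodes the transcription factor PU.1, and PHF12, a component of a histone deacetylase complex, had peaks in both libraries. MYC itself had a peak only at Tet 0 h, and ALKBH5, which encodes an m6A demethylase, had no listed peak in either. SPI1 and PHF12 are known from the study, so their peaks are not independent evidence.

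In the 5' untranslated region of SPI1, a peak at chromosome 11, 47399963 to 47400068, at Tet 0 h had a fold enrichment of 8.23. It lay within a Tet 72 h peak at 47399944 to 47400084, whose fold enrichment in its own list was 30.2. SPI1 had a further peak only at Tet 0 h, at 47376663 to 47376957, which spanned the end of the coding sequence and the 3' untranslated region and had a fold enrichment of 10.0. In PHF12, a coding sequence peak on chromosome 17 was listed at 27239968 to 27240169 at Tet 0 h, with a fold enrichment of 5.95. It overlapped the Tet 72 h peak at 27239897 to 27240146, with 7.53 in that list. The other PHF12 peaks differed in place. At Tet 0 h one lay in the 5' untranslated region at 27278003 to 27278157 with 7.83, and at Tet 72 h one lay in the coding sequence at 27251105 to 27251372 with 9.09. The MYC peak, at chromosome 8, 128750114 to 128750308, carried no transcript-region flag and had a fold enrichment of 5.55. The lowest value in that list was 5.00.

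The last comparison asked which groups of genes lay on either side, for 18 lists fixed before the data were examined. Genes of the NF-kB pathway and interferon-stimulated genes lay farthest from random lists, with more members called only at Tet 72 h than only at Tet 0 h. Across all 5145 genes the opposite held, with a balance of -0.40, the number only at Tet 72 h minus that only at Tet 0 h per gene with a peak. B cell genes also lay above most random lists, though the side with more members changed with the list length. No member of the MYC-activated, m6A machinery, translation factor and chromatin lists had a peak only at Tet 72 h in the whole lists. Across all genes only 542 of 5145 were so called, and none of these groups stood apart there. Their percentiles were 32.9, 8.73, 53.7 and 88.7, in that order.

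NF-kB pathway genes had 22 members with a peak, of which 9 had it in both libraries, 4 only at Tet 0 h and 9 only at Tet 72 h. The balance of 0.227 was above that of 9999 of the 10000 random lists of the same size and equal to that of 1. The members only at Tet 72 h with the highest fold enrichment were the lymphotoxin genes LTB with 21.1 and LTA with 14.4, NFKB1, which encodes the p50 subunit, with 16.1, and EBI3, a cytokine subunit, with 12.7. The other 5, named after their values were seen, were TNF, ICAM1, MAP3K14, BCL3 and IKBKB. The LTB, LTA and TNF genes are neighbours on chromosome 6 with separate peaks. NFKB1 had its peak in the coding sequence at chromosome 4, 103534618 to 103534720. The members only at Tet 0 h were the adaptor genes TRAF2 with 14.2 and TRAF3 with 10.7, and the subunit genes REL with 9.08 and RELA with 6.97. TNIP1 and TNIP2, inhibitors of the pathway, had peaks in both.

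Interferon-stimulated genes had 17 members with a peak, 5 in both libraries, 5 only at Tet 0 h and 7 only at Tet 72 h. Their balance of 0.118 lay at the percentile 99.9, with 4 of the 10000 random lists higher. Among the 7 only at Tet 72 h were OASL with a fold enrichment of 23.0 and IFIT1, which binds viral RNA, with 22.6. The transcription factor IRF1 with 18.7 and IFI44L with 16.1 were also among them. The OASL peak lay in the coding sequence at chromosome 12, 121476654 to 121476755. Only at Tet 0 h were XAF1 with 12.0, the RNA-editing enzyme ADAR with 11.5, PARP9 with 8.72, the signalling gene STAT2 with 7.86 and, named after its value was seen, SP110 with 6.12. ISG15, a ubiquitin-like modifier, had peaks in both, with 36.1 at Tet 0 h and 31.6 at Tet 72 h, as did the exonuclease gene ISG20.

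B cell identity and activation genes had 27 members with a peak, 14 in both, 8 only at Tet 0 h and 5 only at Tet 72 h. Their balance lay at the percentile 98.5, and at 95.6 when peaks without a transcript-region flag were left out. At equal list lengths 3 were called only at Tet 0 h and 9 only at Tet 72 h, at the percentile 97.51. Only at Tet 72 h were RUNX3 with a fold enrichment of 15.5, the chemokine receptor CCR7 with 15.1, the kinases LYN with 12.8 and SYK with 10.2, which act below the B cell receptor, and, named after its value was seen, CIITA with 7.61. Among the 8 only at Tet 0 h were ETS1 with 22.5 and the plasma cell factor XBP1 with 17.3. The early B cell factor EBF1 with 11.5, in a peak without a transcript-region flag, and the adaptor BLNK with 10.3 were also among them. TCF3 and the BAFF and APRIL receptor TNFRSF13B had peaks in both.

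Beside these groups, markers of other cell types were few. Of 14 myeloid markers, LYZ, with a fold enrichment of 9.81, and ITGAM, with 16.1, had a peak, both only at Tet 72 h. The list's percentile of 99.5 rests on these 2 genes, and fell to 96.0 at equal list lengths. Of 17 T cell markers, CD7 alone had a peak, only at Tet 72 h with 6.48, at the percentile 94.95 (1 gene). Of 17 epithelial and fibroblast markers, VIM and ACTA2 had peaks in both and COL1A1 only at Tet 72 h with 5.27, at the percentile 95.5. The ACTA2 peaks carried no transcript-region flag, and 2 members of the list had a peak when such peaks were left out.

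MYC-activated genes had 40 members with a peak, 22 in both, 18 only at Tet 0 h and 0 only at Tet 72 h, at the percentile 32.9. With the Tet 0 h list reduced to equal length, the counts were 17, 15 and 5, at the percentile 4.75. The 5 had Tet 0 h peaks that the reduction left out. Among the 18 only at Tet 0 h were the ribosome biogenesis genes RRP9 with a fold enrichment of 43.1 and WDR43 with 20.4. The nucleoside diphosphate kinase NME1 with 34.0 and the phenylalanyl-tRNA synthetase subunit FARSA with 30.7 were also among them. The arginine methyltransferase PRMT1 and TCOF1 had peaks in both. Genes described as lowered by MYC had 18 members with a peak, 9 in both, 7 only at Tet 0 h and 2 only at Tet 72 h, at the percentile 78.2. At equal list lengths, 2 were called only at Tet 0 h and 4 only at Tet 72 h, at the percentile 81.8. The cell cycle inhibitor CDKN1A with 18.9, the lysosomal regulator TFEB with 11.1, KLF6 with 10.7 and the phosphatase DUSP2 with 10.2 were called only at Tet 0 h. MXD4 with 33.9 and the glucocorticoid-induced TSC22D3 with 14.7 were called only at Tet 72 h, and GADD45B and PDCD4 in both. In the MYC network, with 9 members with a peak, MAX with 12.4, SP1 with 10.2, MGA and MYC were called only at Tet 0 h and MXD4 only at Tet 72 h. HUWE1 and, named after their values were seen, ZBTB17 and TRRAP were among the network genes called in both, and the list lay at the percentile 62.6. At equal list lengths, 1 network member was called only at Tet 0 h and 2 only at Tet 72 h.

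The m6A writers, erasers and readers had 16 members with a peak, 6 in both, 10 only at Tet 0 h and 0 only at Tet 72 h, at the percentile 8.73 (24.8 in the more enriched 50% of each list). The reader IGF2BP1 had a fold enrichment of 15.2, the rRNA methyltransferase ZCCHC4 had 13.9, the writer subunit KIAA1429 (now VIRMA) had 12.6 and the reader YTHDF1 had 12.6, each only at Tet 0 h. The catalytic writer subunit METTL3 and the nuclear reader YTHDC1 had peaks in both. Cell cycle and replication genes had 18 members with a peak, 6 in both, 11 only at Tet 0 h and 1 only at Tet 72 h, at the percentile 17.6 (2.99 with peaks that carried a transcript-region flag). CDK1 with 20.4, the origin factors ORC1 with 15.5 and CDT1 with 15.2, and MCM10 with 14.3 were called only at Tet 0 h, the CDK inhibitor CDKN2D with 5.53 only at Tet 72 h, and the helicase subunits MCM3 and MCM5 in both.

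Translation factors had 38 members with a peak, 23 in both and 15 only at Tet 0 h, at the percentile 53.7 (5.95 at equal list lengths). Those only at Tet 0 h included the initiation factor EIF1AX with 38.3, the kinase EIF2AK1 with 24.2, EIF2S2 with 22.5 and EIF2B5 with 18.1, while EIF5B and EIF4E2 had peaks in both. Chromatin regulators had 46 members with a peak, 33 in both and 13 only at Tet 0 h, at the percentile 88.7. The remodeller subunit SMARCC1 with 20.0, the H3K27 methyltransferase EZH2 with 19.4, the demethylase KDM4B with 15.5 and the H3K36 methyltransferase SETD2 with 14.1 were called only at Tet 0 h, and KDM1A and BRD2 in both. At equal list lengths 10 chromatin regulators were called only at Tet 72 h and 4 only at Tet 0 h, and 2 translation factors only at Tet 72 h. In the whole lists 0 members of either group were called only at Tet 72 h, so these 10 and 2 had Tet 0 h peaks that the reduction left out.

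Ribosomal protein genes had 30 members with a peak, 17 in both, 11 only at Tet 0 h, led by RPL15 and RPL37, and 2 only at Tet 72 h, RPS19 and RPL13, at the percentile 79.8. These genes have many processed pseudogenes, which can share their reads. Glycolysis, glutamine and nucleotide genes had 23, of which 10 were called in both, such as the glucose transporter SLC2A1, 11 only at Tet 0 h, led by the phosphofructokinase PFKM, and 2 only at Tet 72 h, UMPS and GLUL, at the percentile 53.8. Apoptosis regulators had 17, 8 in both, including BAX and FADD, 8 only at Tet 0 h, led by BID and BAK1, and 1 only at Tet 72 h, HRK, at the percentile 49.6. Lysosome and autophagy genes had 11, 5 in both, including SQSTM1, 5 only at Tet 0 h, led by GAA, and 1 only at Tet 72 h, ATG9A, at the percentile 59.5. At equal list lengths, 2 apoptosis regulators were called only at Tet 0 h and 3 only at Tet 72 h, and 3 and 4 lysosome and autophagy genes. The 4 study genes, with 3 members with a peak, lay at the percentile 59.1 (96.1 at equal list lengths, with 2 members).

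**Figure D3:**
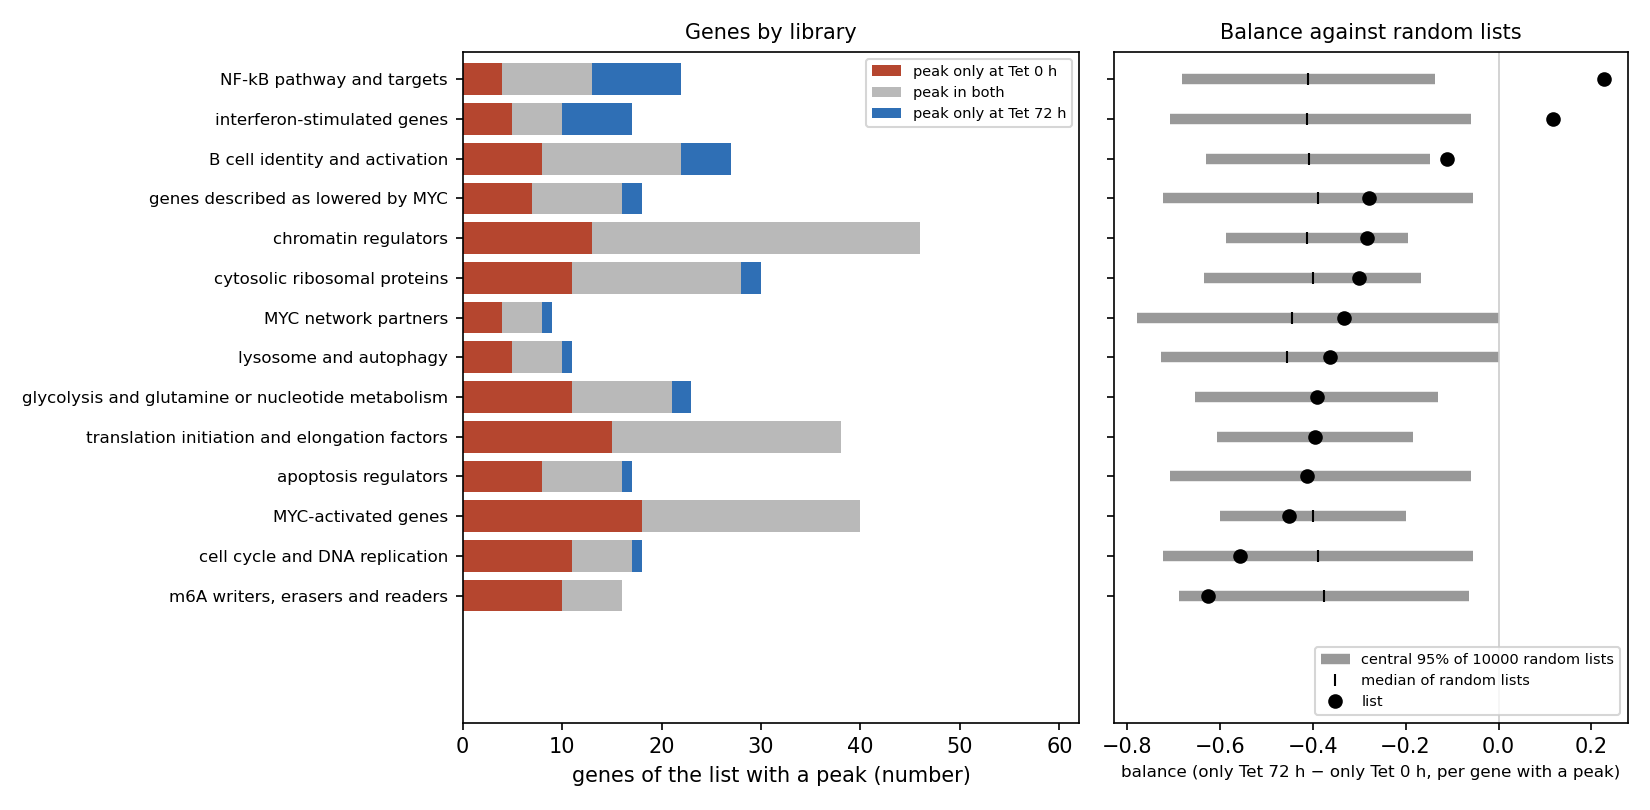
For the gene lists with at least 9 members with a peak, the number of genes with a peak only at Tet 0 h, in both or only at Tet 72 h, and the balance of each list against the central 95% of 10000 random lists of the same size. The NF-kB and interferon lists have balances of 0.227 and 0.118, above 0, and all other lists drawn lie below 0. The B cell and chromatin lists, among others, lie above 0 at equal list lengths, where weaker Tet 0 h peaks are left out.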

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

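The comparisons regardless of strand, with random lists of mRNA genes only, with genes left out of the lists where their peaks in both libraries did not overlap, with peaks shared between different genes, and with random lists matched on the rank of fold enrichment were chosen after seeing the data. Of 181 values under an alternative, 145 stayed within a tolerance, 32 moved, and 3 lost and 1 gained a place beyond the percentile limits. Most that stayed, 121 of the 145, were gene-list percentiles, which can change widely on the same side of the limits. Of 21 flag shares 17 moved and 4 stayed, and of 35 other values 15 moved and 20 stayed. The tolerance was the 95% interval for shares, 1.5 times for counts, the quartiles for medians and the side of the limits for gene lists. The sign of the balance is a separate matter. It changed for 7 of 18 lists at equal lengths, namely B cell genes, chromatin regulators, apoptosis regulators, lysosome and autophagy genes, MYC network partners, genes described as lowered by MYC and the study genes, and for 2 of 17 in the more enriched 50%, B cell and study genes. T cell markers had no value in the more enriched 50%.

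A reciprocal overlap of 50% lowered the overlapped share to 28.3% of Tet 0 h and 55.8% of Tet 72 h peaks. In the more enriched 50% of each list (3544 and 1796 peaks) it was 29.9% and 59.0%, with 1027 genes in both and 1681 only at Tet 0 h. Set against the whole other list, that part gave 1267 genes only at Tet 0 h and 234 only at Tet 72 h. With both lists at 3592 peaks the shares were 41.2% and 41.3%, with 1288 and 1079 genes in 1 library only, and 21.3% of Tet 0 h genes had more than 1 peak. By construction, the more enriched 50% and equal lengths hold fewer peaks.

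For the flags of Tet 0 h peaks, the more enriched 50% gave TcSS 3.16%, 5'UTR 26.7%, coding start 18.1%, coding sequence 77.2%, coding end 5.19%, 3'UTR 11.5% and none 7.08%. Equal lengths gave 26.6%, 18.0%, 77.3%, 5.21%, 11.5% and 7.04% for the last 6. At Tet 72 h the more enriched 50% gave 5'UTR 27.7%, coding start 19.0%, coding end 4.51% and 3'UTR 9.63%.

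The B cell list fell to the percentile 95.6 with peaks carrying a flag, and the myeloid list to 96.0 at equal lengths and 92.9 in the more enriched 50%, where chromatin regulators rose to 98.1. The cause was not tested. The balance of all genes was -0.05 at equal lengths. No paired analysis was possible because each condition had 1 library. Exon blocks, gene assignment from a reference annotation, sequence motifs and matching on exonic length were not run. Unknown depth limits every count of genes in 1 library only.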

Other observations

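The gene families, the chromosome and the gene types in the next 2 paragraphs were chosen after seeing the data. So were the test of transcript abundance and the test of a single difference in sensitivity.

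Among 14 families defined by their symbols, 5 lay above the upper percentile limit and 0 below the lower one. Of 13 HLA genes with a peak, 9 were called in both libraries, 1 (HLA-H) only at Tet 0 h and 3 only at Tet 72 h, at the percentile 99.8 of random lists. Those only at Tet 72 h included HLA-DQB1, with a fold enrichment of 26.0, and HLA-DRB5, with 20.1, genes with close relatives whose reads can be shared. Integrins had 6 genes with a peak, of which ITGAM, ITGAX, ITGB2 and ITGB7 were called only at Tet 72 h and ITGAE only at Tet 0 h. Of 5 chemokine or chemokine receptor genes, CCR7, CCR10 and CXCR3 were called only at Tet 72 h and 0 only at Tet 0 h. Genes named as CD antigens had 14 in both, 5 only at Tet 0 h and 6 only at Tet 72 h, at the percentile 99.9. Other families of surface proteins did not stand apart. The TNF ligand and receptor superfamily had 5 only at Tet 0 h and 1 only at Tet 72 h, at the percentile 58.3, interleukins and their receptors had 4 and 1, at 63.2, and solute carriers had 32 and 5, at 26.5.

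Mitochondrial ribosomal protein genes had 12 in both, 20 only at Tet 0 h and 0 only at Tet 72 h, at the percentile 2.68, which did not pass the limit of 2.5. MRPL35, with a fold enrichment of 34.3, MRPL22, with 27.5, and MRPS15, with 26.1, led those only at Tet 0 h. Zinc finger genes with a ZNF symbol had 31 in both, 72 only at Tet 0 h and 13 only at Tet 72 h, at the percentile 4.45, also within the limits. Ubiquitin-specific proteases lay at the percentile 98.6, with 9 genes in both, 3 only at Tet 0 h (USP31, USP34 and USP36) and 3 only at Tet 72 h (USP5, USP8 and USP11). Peaks on chromosome 19 were 12.6% of those at Tet 0 h (11.8 to 13.3%) and 15.8% of those at Tet 72 h (14.6 to 17.0%). Of 65 lincRNA genes with a peak, 26.2% were called only at Tet 72 h, against 9.74% of 4742 mRNA genes. The share was 22.6% of 106 antisense genes and 19.0% of 58 processed transcripts.

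NF-kB pathway and interferon-stimulated genes were shifted to Tet 72 h in the report. The settings were lists of equal length, the more enriched peaks and peaks in an annotated transcript region. Over them, the lowest percentile was 99.46 for the NF-kB list and 99.585 for the interferon list. This cannot decide whether unequal lengths or thresholds made the shift. The random lists came from the same peak lists, so a difference common to all genes cancels. Only the setting of equal length equalised the number of peaks, and its cut was higher at Tet 0 h than at Tet 72 h. The values show only that the NF-kB and interferon genes kept their shift in each setting. More transcript of these genes at Tet 72 h, with no more methylation of each, remains open. The samples hold an input library at Tet 0 h only, and its values were not used here. With no input library at Tet 72 h, where 1 at each time would be needed, transcript abundance and methylation cannot be told apart. A change of methylation with the MYC level is untested for the same reason.

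The longer list at Tet 0 h may reflect a lower sensitivity of peak calling at Tet 72 h. Genes called in both libraries also had more peaks at Tet 0 h, by a ratio of 1.29, which that explanation predicts, although a wider methylation of each transcript would give the same. Whether a single difference in sensitivity, with no change of the genes that carry peaks, is the whole account cannot be decided here. The criterion was set after the data were seen, and each condition had 1 library. The NF-kB and interferon lists, 2 of 18, stayed above the upper percentile limit in every setting run, also among random lists matched on the rank of fold enrichment. Of the genes called in 1 library, 69.2% of the NF-kB list (42.4 to 87.3%) and 58.3% of the interferon list (32.0 to 80.7%) were called only at Tet 72 h. In 10 equal parts of all genes by that rank, this share was at most 20.6% (17.3 to 24.4%). The shares of the 2 lists rest on the same counts as their balances, so they add no separate support. The random lists also take genes as independent, which genes of 1 pathway may not be. A difference in depth, a change of transcript abundance between times and a change of methylation with MYC remain open. Variation between single cultures or libraries also remains open, since each condition had 1 library.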
